A study of Mus musculus with 4 samples.

How the data were processed

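The series is a chromatin immunoprecipitation and sequencing (ChIP-seq) experiment on formaldehyde-fixed spleen cells of C57BL6 mice. It has 4 samples, an immunoprecipitation with an antibody against ERG and one with control rabbit IgG from each of 2 leukemias. Leukemia 1 is labelled transgenic and leukemia 2 transgenic GATA1s. Groups were taken from the genotype and antibody labels, which gives 1 library per group.

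The 2 files analysed here are peak lists. Each carries the title of 1 ERG sample in its name, apart from the spelling of leukemia, and it was assigned to that sample. No values of the IgG libraries were used here. Reads were aligned with Bowtie to the mouse build mm9, per the submitters' processing notes. The peak caller, its threshold, any filter and the way the IgG libraries entered the calling are not given in the sources used here. The lists have no header and hold a chromosome, a start and an end for each peak. As deposited by the authors, every interval is 400 bp wide, so the width carries no information and the true extent of each enriched region is unknown. No height, fold, score or p-value accompanies a peak, and no read depth was used here, so the depth behind each call is unknown. Each list was taken to come from the 1 library it is named for.

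The gene table at hand is for the assembly GRCm38.p6, not mm9. On 3 of the 20 chromosomes (5, 7 and 8) peaks lay beyond the last gene of that assembly, 42 peaks of leukemia 1 and 29 of leukemia 2. Coordinates were not converted between builds. The planned annotation of peaks by gene, promoter, exon and intron, the motif search and the counts near listed genes were therefore not run, and regions are named by mm9 coordinates counted from 1.

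Peak lists were compared by position. A peak was called shared when it overlapped a peak of the other list by at least 1 bp, which for intervals of 400 bp means centres less than 400 bp apart. The chance level came from 1000 random placements of the other list within each chromosome, between the first and the last peak of either list. A further chance level came from moving the other list by 10 kb or 100 kb in both directions, which keeps the regional density of peaks. Spacing was measured between neighbouring centres of a list. The clustering distance was 12500 bp. A cluster was a run of peaks with no gap over that distance between centres, and the number of peaks with a neighbour within it was set against 1000 random placements. The number of peaks per chromosome was compared between the lists with two-sided Fisher's exact tests and Benjamini-Hochberg adjustment over 20 chromosomes. Shared peaks enter both lists, so the lists are not independent in that test, and peaks found in 1 list alone were tested as the alternative. The planned comparison of peak scores was not made, as no score is given.

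Other tests were added after the lists had been compared. Those reported with the additional observations are Fisher's exact tests of the share of each list found in the other on each chromosome, 3 permutation tests of the evenness of shares over chromosomes with 10000 permutations and 1 more without chromosome 11, 3 correlations of peak density with that share over chromosomes, 3 tests of chromosomes 17 and 19, together and apart, against chromosome 11, 6 tests of the number of peaks around shared and unshared peaks, 6 tests of neighbouring peaks, the windows richest in peaks of 1 list, and the search for displaced peaks. The distances from peaks of 1 list to shared peaks and the counts of windows with 5 or more peaks, both set against random placement, and the count of displaced peaks were also added then and stand in the results, marked as such.

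Shares are given with 95% Wilson intervals. These cover counting error only, since peaks are not replicates and there is 1 library per group. No test here compares the genotypes, and p-values compare the 2 lists or describe peaks within a list.

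The regions named were chosen by a rule fixed before the data were examined: the 5 windows of 100 kb with most peaks in each list, with ties kept. The highest-scored and the widest peaks of that rule could not be chosen, because no score is given and all widths are equal. The clusters of 5 or more peaks were chosen after their values were seen. Alternatives were another overlap rule, another chance level, other spacing limits and peaks of 1 list alone. Alternatives that need a score were not run. The computations used Python 3.11.15, NumPy 2.4.6 and SciPy 1.17.1, and plots were drawn with matplotlib 3.10.9.

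The functions were tested on simulated data with known answers. Of 2818 peaks planted in both of 2 simulated lists, 2819 were found shared, the excess coming from chance overlap. Of 2856 peaks planted with a neighbour, the search found 2905, including chance neighbours. Planted centres were moved by less than the overlap limit, and planted neighbours lay within the clustering distance. Full recovery therefore followed from the settings, and larger displacements were not tried. Chromosome 11, which held most peaks, was raised 1.5 times in 1 list and passed the adjusted Fisher test in 100% of 100 draws. Chromosomes with fewer peaks were not tried. With none raised, some chromosome passed in 7% of draws. The simulated lists were drawn independently, whereas the real lists have shared peaks, so these rates do not carry over to the reported test.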

Results

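ERG binding was mapped by ChIP-seq in spleen cells of 2 mouse leukemias that carry an ERG transgene. ERG is a transcription factor of the ETS family with a role in blood stem cells and megakaryocytes. Leukemia 1 was labelled transgenic. Leukemia 2 was labelled transgenic GATA1s, the usual name of a short isoform of the blood transcription factor GATA1 that lacks the N-terminal activation domain. Each leukemia had 1 ERG library and 1 IgG library, so no value below has a replicate. The data are the authors' peak positions on mm9, without peak heights or read depth. The comparison that the design implies is which regions ERG occupied in both leukemias and which in only 1.

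ERG peaks were more numerous in leukemia 1 than in leukemia 2. The list of leukemia 1 held 5738 peaks and that of leukemia 2 held 3751, a ratio of 1.53. At the fixed width of 400 bp the lists covered 2.3 Mb and 1.5 Mb. Peaks lay on 19 autosomes and chromosome X in both lists, 20 chromosomes in all. The median distance between neighbouring centres was 91.2 kb in leukemia 1 and 160.4 kb in leukemia 2. Without replicates or depth, the difference in number cannot be set against an error.

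Most ERG peaks of leukemia 2 were also peaks in leukemia 1. The lists shared 3201 regions, each matching exactly 1 peak of the other list. These were 85.3% of the peaks of leukemia 2 (95% Wilson interval 84.2 to 86.4) and 55.8% of those of leukemia 1 (54.5 to 57.1). A further 2537 peaks were found in leukemia 1 alone and 550 in leukemia 2 alone, although 45 of the 550 had a leukemia 1 centre 400 to 1000 bp away, a count made after the lists were seen. The 2 lists together marked 6288 regions, of which 50.9% were shared. Random placement of the other list gave a mean of 7.5 shared peaks for leukemia 1 (range 1 to 18) and 7.7 for leukemia 2 (range 1 to 20). Moving the other list by 10 kb gave 31.5 shared peaks and moving it by 100 kb gave 22.5. The observed number was thus 102-fold above the list moved by 10 kb.

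Most shared regions were located at nearly the same base pairs in both leukemias. The median distance between the 2 centres of a shared region was 12 bp, with quartiles of 5 and 32 bp. Centres lay under 50 bp apart at 2631 shared regions (82.2%) and coincided exactly at 103. The 90th percentile was 94 bp. From 225 to 400 bp each bin of 25 bp still held 2 to 10 shared regions, so a thin tail reached the overlap limit. The centre of leukemia 2 lay at the higher coordinate at 1547 regions and at the lower at 1551, so neither list was displaced as a whole.

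**Figure D1:**
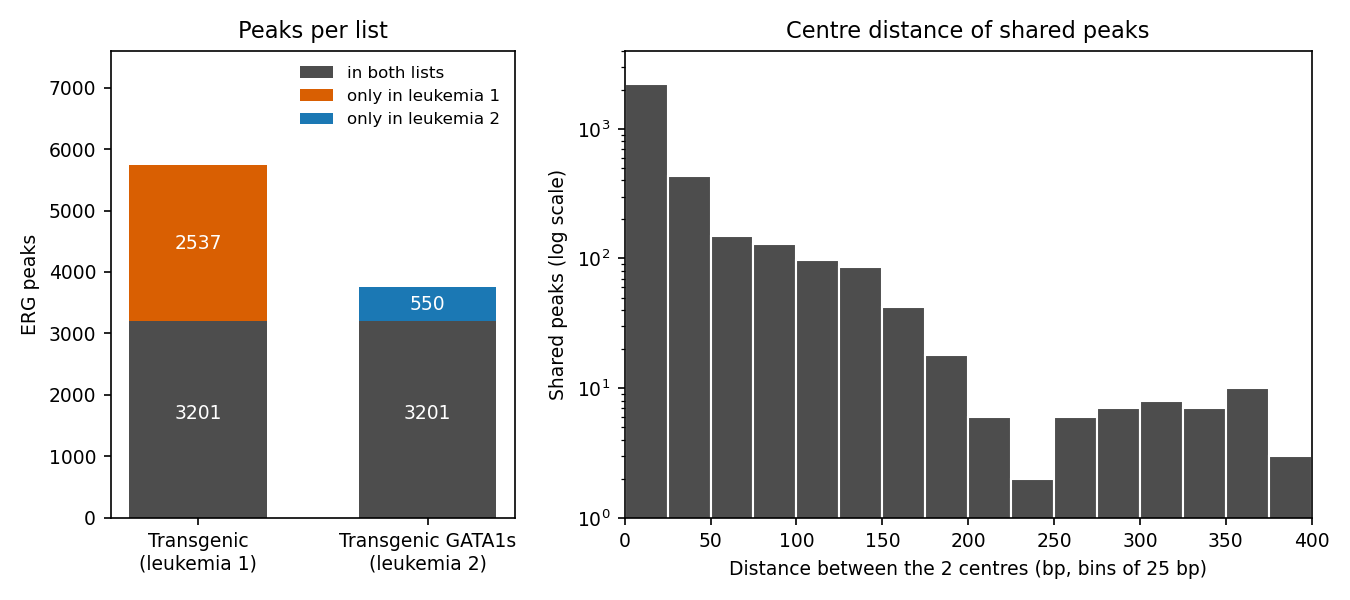
Left, ERG peaks in each list (y axis, number of peaks), split into peaks found in both lists and in 1 list; right, number of shared peaks (log scale) by the distance between their 2 centres in bp. The 3201 shared peaks make up most of the shorter list, and 2200 of them have centres less than 25 bp apart.

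Chromosome 11 carried more ERG peaks than any other chromosome in both leukemias. It held 561 peaks of leukemia 1 (9.78% of the list) and 312 of leukemia 2 (8.32%), or 4.74 and 2.64 peaks per Mb between the first and the last peak of the chromosome. Chromosome 17 followed in leukemia 1 with 3.55 peaks per Mb and chromosome 19 with 3.29. In leukemia 2 chromosome 19 had 2.34 peaks per Mb and chromosome 17 had 2.13. Chromosome X was the sparsest, with 88 peaks in leukemia 1 and 48 in leukemia 2, or 0.55 and 0.30 per Mb. The ratio of leukemia 1 to leukemia 2 peaks ran from 1.36 on chromosome 18 to 1.83 on chromosome X, and was 1.80 on chromosome 11. Fisher's exact test for a different share of the 2 lists, adjusted over 20 chromosomes, passed for 0 chromosomes. Shared peaks enter both lists, which draws the shares together, so this does not show that they were equal. The lowest adjusted p of these exact tests was 0.33, for chromosome 11 (unadjusted p = 0.0165, the only chromosome of the 20 under 0.05). Among peaks found in 1 list alone, chromosome 11 held 11.4% of those of leukemia 1 and 7.45% of those of leukemia 2 (Fisher's exact test, unadjusted p = 0.00607, adjusted p = 0.121).

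**Figure D2:**
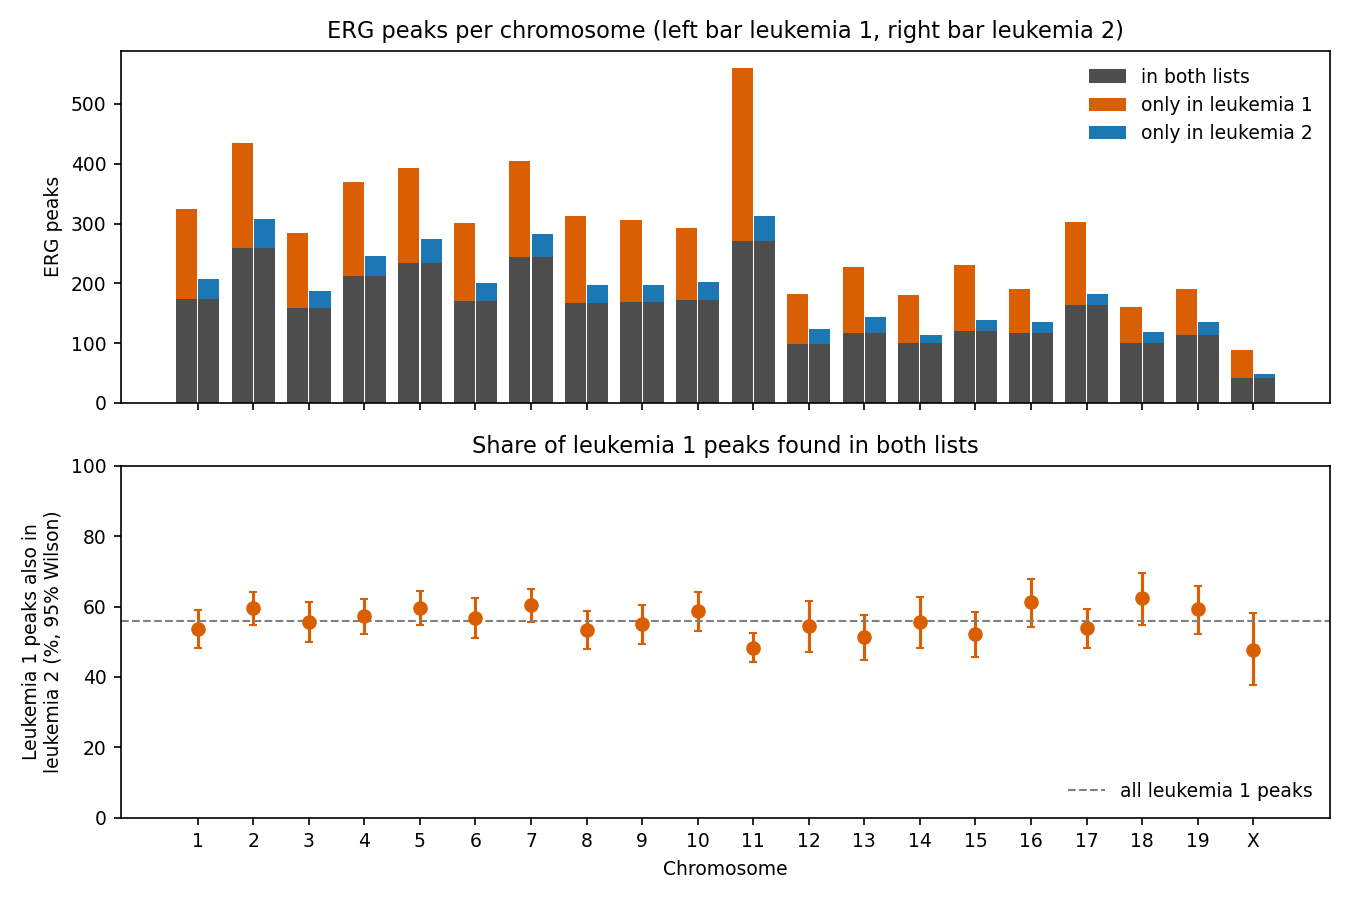
Top, ERG peaks per chromosome (y axis, number of peaks) in leukemia 1 (left bar) and leukemia 2 (right bar), split into peaks found in both lists and in 1 list; bottom, percentage of leukemia 1 peaks that were also found in leukemia 2, with 95% Wilson intervals and the value for all leukemia 1 peaks as a dashed line. Chromosome 11 has the tallest bars, 561 and 312 peaks. Of its leukemia 1 peaks 48.3% are shared, against 55.8% over the whole list and 47.7% on chromosome X. These shares were tested only after the planned test of peaks per chromosome had passed for 0 of 20 chromosomes.

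ERG peaks were clustered along the chromosomes in both leukemias. In leukemia 1, 1432 peaks (25%, 23.9 to 26.1) had a neighbour within the clustering distance, against 355 under random placement (range 284 to 448), a 4.03-fold excess. In leukemia 2, 627 peaks (16.7%, 15.6 to 17.9) had such a neighbour, against 151 (range 100 to 203), a 4.16-fold excess. Both counts exceeded each of the 1000 placements. Random placement did not keep the regional density of peaks. The excess therefore cannot tell close grouping of peaks from uneven density over larger regions. Most clusters were pairs. Leukemia 1 had 536 pairs, 88 runs of 3 peaks and 22 runs of 4 or more, and leukemia 2 had 245, 37 and 6. Very close neighbours were rare: 10 neighbouring pairs of leukemia 1 and 6 of leukemia 2 lay under 1000 bp apart, against 115 and 48 pairs at 1000 to 2000 bp. The smallest distance between centres was 580 bp in leukemia 1 and 549 bp in leukemia 2. Peak calling and any filter are not known, so this scarcity cannot be read as the spacing of ERG sites.

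The largest cluster lay on chromosome 10 at 79603961 to 79635892, with 6 peaks of leukemia 1 and 4 of leukemia 2 over 31.9 kb, of which 3 were shared. The cluster on chromosome 18 at 60661916 to 60685979 had 5 peaks in each leukemia, and all 5 were shared. On chromosome 5 at 117583399 to 117599712, each leukemia had 5 peaks, of which 4 were shared. On chromosome 11 at 94850970 to 94873808, leukemia 1 had 5 peaks and leukemia 2 had 4, and all 4 were shared. On chromosome 9 at 107444052 to 107474301, leukemia 1 had 5 peaks and leukemia 2 had 4, with 3 shared. Clusters on chromosome 11 at 115936818 to 115955423 and on chromosome 17 at 28344616 to 28369759 each had 5 peaks of leukemia 1, of which 2 were the only peaks of leukemia 2 there.

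**Figure D3:**
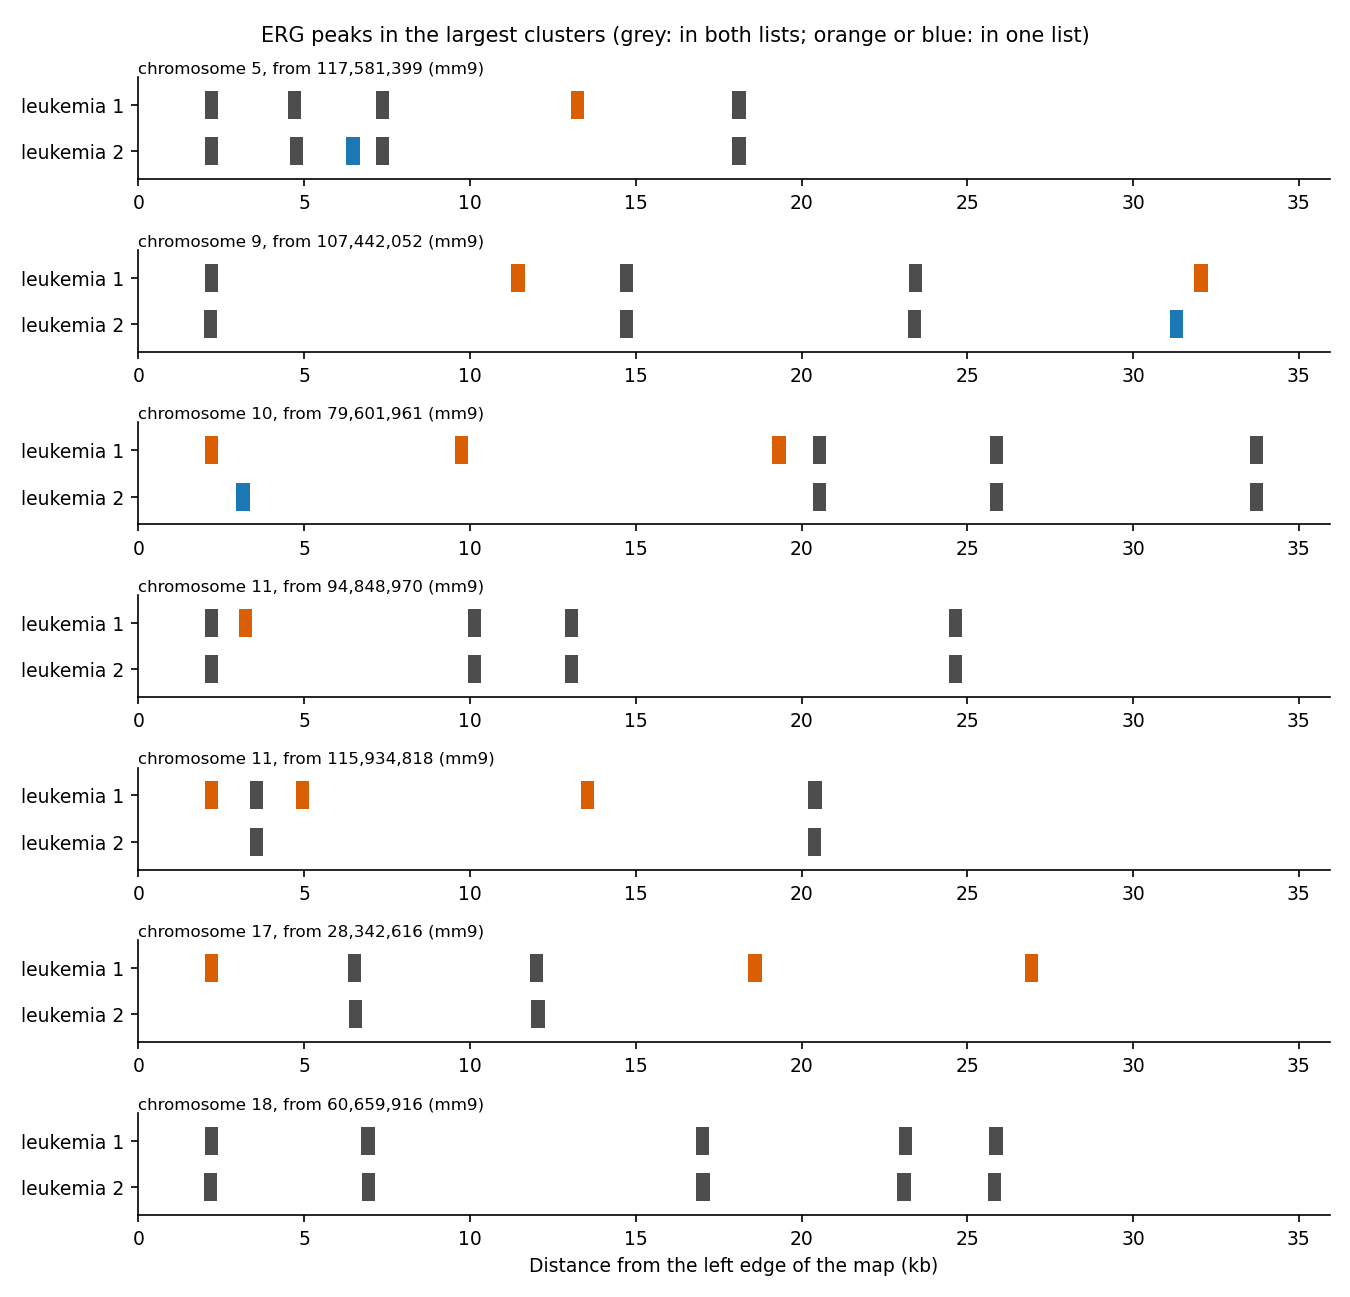
Positions of ERG peaks (boxes of 400 bp, to scale) of leukemia 1 (upper row) and leukemia 2 (lower row) in the 7 clusters with 5 or more peaks, with the distance from the left edge of each map in kb. All 5 peaks of the cluster on chromosome 18 are shared, while 3 of the 5 leukemia 1 peaks on chromosome 17 have no counterpart in leukemia 2. The unshared leukemia 2 peaks on chromosomes 5, 9 and 10 each lie within 1 kb of a leukemia 1 peak and may be displaced calls.

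Dense windows were found in both lists. On a fixed grid of 100 kb, 42 windows of leukemia 1 held 5 or more peaks, against a mean of 0.309 and at most 3 under random placement, a count added after the lists were seen. In leukemia 2 there were 12 such windows, against 0.027 and at most 1. This random placement did not keep the regional density of peaks either. The highest count in a single window was 7 in leukemia 1, against at most 6 under random placement, and 6 in leukemia 2, where random placement reached 7. In leukemia 1 the 5 densest windows held 7 peaks each. They began at 16800001 on chromosome 7, 107400001 on chromosome 9, 79600001 on chromosome 10, 120400001 on chromosome 11 and 8800001 on chromosome 19. Leukemia 2 had 5, 5, 5, 4 and 3 peaks in these windows, and 5, 4, 3, 4 and 3 of the leukemia 1 peaks there were shared. The densest window of leukemia 2 began at 80000001 on chromosome 10 and held 6 peaks, 5 of them shared. The other windows of leukemia 2 with 5 peaks each were tied. In those beginning at 125000001 on chromosome 5, 16800001 and 52300001 on chromosome 7, and 35000001 and 60600001 on chromosome 18, all 5 peaks were shared. In those beginning at 117500001 on chromosome 5, 107400001 on chromosome 9 and 4000001 on chromosome 19, 4 of 5 were shared. In those beginning at 83000001 on chromosome 6 and 79600001 on chromosome 10, 3 of 5 were shared. The window beginning at 117600001 on chromosome 11 shared 2 of its 5 peaks.

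The distance to shared regions was compared with random placement after the lists were seen, and the excess was not particular to peaks found in 1 leukemia alone. Of the 3201 shared regions, 445 (13.9%) had another within the clustering distance, against a mean of 111 under random placement. Of the peaks found in leukemia 1 alone, 15.2% (13.8 to 16.6) had a shared peak within the clustering distance, against 3.32% under random placement. Of those found in leukemia 2 alone, 16.4% (13.5 to 19.7) had one, against 3.13%. Within 1 kb, 0.236% of the peaks of leukemia 1 alone and 0.909% of those of leukemia 2 alone had a shared peak, against 0.288% for both under random placement. These shares at 1 kb cannot be compared with random placement. Peaks of 1 list alone lie at least 400 bp from any centre of the other list by definition. Within a list the smallest distance between centres was 580 bp in leukemia 1 and 549 bp in leukemia 2. Random positions had no such limit. Within 50 kb the shares were 39.2% (37.3 to 41.1) and 40.5% (36.5 to 44.7), against 11% and 10.8% under random placement. Regional density of peaks was not kept in these placements, so it may account for part of each excess.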

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

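The number of shared peaks, 3201 in the main comparison, ran from 2642 to 3217 in the alternatives for which it was counted. It was 3152 with at least 50% overlap (the shorter-peak and the reciprocal rule are the same for equal widths). With centres within 500 bp it was 3217, with centres within 50 bp 2642, and without chromosome 11 it was 2930. The 50 bp rule and the omission of chromosome 11 were chosen after seeing the data. Merging peaks within 100 bp joined none. The chance level rose from 7.5 and 7.7 shared peaks to 31.5 (list moved by 10 kb) and 22.5 (by 100 kb), both far under 3201. The excess of peaks with a neighbour over random placement changed with the distance: 4.67-fold within 5 kb and 2.52-fold within 50 kb in leukemia 1 (4.03-fold at the clustering distance), and 4.70-fold and 2.96-fold in leukemia 2 (4.16-fold). After seeing the data it was also computed for peaks found in leukemia 1 alone (4.66-fold), in leukemia 2 alone (7.04-fold, on 22 clustered peaks) and for shared peaks (4.03-fold). The cause was not tested. No chromosome passed the adjusted test among all peaks or among peaks of 1 list. In tests added after seeing the data, the permutation p for an uneven share of leukemia 1 peaks found in leukemia 2 across chromosomes was 0.0085, and 0.234 without chromosome 11, which says little, since the chromosome left out was chosen as the most extreme. The adjusted Fisher p for chromosome 11 was 0.00242 to 0.00471 under 3 other overlap rules (at least 50% overlap, centres within 500 bp and centres within 1000 bp). The alternatives with the better-scored part of each list or equal list lengths need a score, and those on location, motifs and gene lists need an mm9 genome or annotation; these were not run. No paired analysis was possible because each group has 1 library. Unknown depth and threshold limit what the absence of a peak from a list can show.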

Other observations

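All tests in this part were chosen after the lists had been compared. Only for the shares along 3 equal parts of chromosome 11 was the expected outcome written down before the values were seen.

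Windows of 100 kb with 4 peaks of leukemia 1 and none of leukemia 2 began at 21800001 on chromosome 3, and at 115000001 and 121000001 on chromosome 5. A window beginning at 148300001 on chromosome 7 had 3 peaks of leukemia 2 and none of leukemia 1. Permuting within chromosomes which peaks were shared gave windows as rich in peaks of 1 list in 100% of permutations for leukemia 1 and in 66.2% for leukemia 2. The mean number of other peaks within the clustering distance was 0.293 around shared and 0.318 around unshared peaks of leukemia 1, and 0.19 and 0.227 in leukemia 2. No difference was detected in 6 such permutation tests at the clustering distance, 50 kb and 500 kb (lowest p = 0.0809, adjusted p = 0.218).

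Chromosome 11 of leukemia 1 had a low share of peaks found in leukemia 2. Of its 561 peaks, 48.3% (44.2 to 52.4) were found, against 56.6% (55.2 to 57.9) on the other chromosomes together (two-sided Fisher's exact test, p = 0.0002, adjusted p = 0.00399 over 20 chromosomes). The planned test of peaks per chromosome had passed for 0 of 20 chromosomes, and this one was added after that result. Chromosome X had a lower share, 47.7% (37.6 to 58.0) of 88 peaks, with an adjusted p of 0.395. Of the leukemia 2 peaks on chromosome 11, 86.9% (82.7 to 90.2) were shared, against 85.2% elsewhere (Fisher's exact test, adjusted p = 0.931). Evenness over the 20 chromosomes gave a permutation p of 0.0085 for the leukemia 1 list (0.0255 adjusted over 3 tests), 0.903 for the leukemia 2 list and 0.203 for peaks of 1 list alone. Neighbouring peaks of a library are not independent, which these p-values do not take into account.

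No trend of the share of leukemia 1 peaks found with peak density was detected over 20 chromosomes, which does not exclude one. On chromosomes 17 and 19, the next densest, 55.9% (51.5 to 60.2) of leukemia 1 peaks were shared, more than on chromosome 11 (two-sided Fisher's exact p = 0.016), but their shares were known when that was tested. Apart, chromosome 19 was at 59.2% (52.1 to 65.9, exact p = 0.0118) and chromosome 17 at 53.8% (48.2 to 59.3, exact p = 0.134). Over 20 chromosomes, peak density and the share found had a Pearson r of -0.01 (permutation p = 0.965) and a Spearman rho of 0.14 (p = 0.548), with an r of 0.11 (p = 0.661) without chromosomes 11 and X (adjusted p = 0.965 for each of these 3). The shares in 3 equal parts of chromosome 11 were 46.1% (36.1 to 56.4), 45.7% (38.6 to 52.9) and 50.7% (44.9 to 56.4), but they divide the same peaks that had drawn attention by their low share. They therefore do not decide on a change over the whole chromosome, such as an extra copy in leukemia 1, and copy number was not measured.

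Some peaks called in leukemia 2 alone may be sites of leukemia 1 called at a displaced centre. Of the 550, 45 had the nearest leukemia 1 centre at 400 to 1000 bp, against a mean of 1.73 and at most 6 in 200 random placements, and 7.5 per 100 bp of distance against 2 per 100 bp at 1000 to 2000 bp. Regional density of peaks was not kept in these placements, so it may account for part of the excess over them. Within 5 kb, 109 of the 550 had a leukemia 1 centre, against a mean of 12.8 under random placement. These 45 are 8.18% (6.17 to 10.8) of the 550, but for 5 of them the leukemia 1 peak already matched another leukemia 2 peak, so displacement on this scale covers at most 40, or 7.27% (5.39 to 9.75), and leaves 510, with separate sites side by side still open for the 40. The list of leukemia 1 was 1.53 times as long as that of leukemia 2. Each label has 1 library, and no peak has a height. Depth, calling threshold, the GATA1s label and any other difference between the 2 leukemias therefore cannot be told apart as reasons. The 14.7% (13.6 to 15.8) of leukemia 2 peaks absent from leukemia 1 does not decide between them.

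The hypothesis that ERG peaks were gained or lost together over regions was tested on neighbouring peaks within the clustering distance. In leukemia 1, 50.4% of 786 pairs were alike in being shared or not, against a mean of 50.7% in 1000 permutations (range 45.5 to 56.5). In leukemia 2, 72.3% of 339 pairs were alike, against 75.4% (67.3 to 82.0). With 5 and 50 kb included, 6 tests were run, and the lowest one-sided permutation p for more pairs alike was 0.153. The lowest two-sided permutation p was 0.033 (adjusted p = 0.198), in the opposite direction, for leukemia 2 within 5 kb, where 68.2% of 151 pairs were alike against 75.5% (64.2 to 85.4). These ranges leave smaller regional effects open.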
